A study of Mus musculus with 2 samples.

How the data were processed

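Total RNA depleted of ribosomal RNA was sequenced from the hippocampus of 14-day-old female B6CASTF1/J mice, with ERCC spike-ins (synthetic RNAs added in known amounts) in each library. The series held 1 group of 2 libraries, named biological replicates 1 and 2 per the labels. The source is described per the labels as a layer of the hippocampus, with no statement of which; it is called hippocampus throughout. Each library lists 3 females, with different mouse numbers, and 300 ng of RNA went in. Whether the listed females were combined before or after RNA extraction is not given in the sources used here. Both libraries carry the same donor identifier in the labels. RNA was purified with a Norgen animal tissue kit per the labels. Nothing in the labels says that the spread between these libraries is more than replicate spread.

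The authors quantified each library against the mm10 mouse assembly and the GENCODE M21 annotation per the file headers and the accompanying notes. The deposited gene and transcript tables of the first quantification have the layout of RSEM output and were made from alignments to the transcriptome. They give expected counts (estimated reads per gene, which need not be whole), TPM and FPKM per the file headers, and for each transcript its percent of the gene's TPM. Length and effective length differed by 99 in these tables, as a fixed fragment length gives. The second quantification is a deposited transcript table in the layout of kallisto output, made from the reads themselves, with estimated counts and TPM per the file headers. Its lengths and effective lengths differed by 343.1 in replicate 1 and 346.1 in replicate 2. The aligner, the tool versions and the use of strand in counting are not given in the sources used here. Antisense and overlapping genes are therefore treated as uncertain, and so are genes that share sequence with copies. TPM was computed by the authors over all entries, the spike-ins included. The mm10 sequence is that of C57BL/6J; reads from CAST/EiJ alleles carry more differences from it, and expression by allele was not analysed here. Alignments and signal tracks were not used here.

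Depth was 33465393 expected counts in replicate 1 and 32879872 in replicate 2, and 33783523 and 33023798 estimated counts in the second quantification. Of the first, 33321573 and 32740837 fell on 55536 annotated genes. ERCC spike-ins took 143817 and 139031 counts. The bacteriophage phiX entry had 0 and 1 counts, and 26248 entries that carry only a numeric identifier had 3 counts in each library together. These entries stayed out of library sizes and comparisons. A floor of 3 counts corresponds to 0.131 TPM in replicate 1 and 0.132 TPM in replicate 2 for a gene with 1 kb of effective length. Intervals and floors cover counting error only, at 95% confidence, since reads are not independent molecules.

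The gene lists, the ratios, the isoform genes, the thresholds and the alternatives of the first round were chosen before the data were examined. Levels are the mean ± SD over the libraries (n = 2); for a gene list, the median over members of their mean TPM, with the SD of the libraries' own medians. A gene counted as detected at a TPM of at least 1 in both libraries. Replicate spread was estimated with edgeR 4.0.16 in R 4.3.3 (estimateDisp, intercept only, TMM scaling) on expected counts rounded to whole numbers, for genes with at least 10 counts in each library. A robust coefficient of variation used genes with at least 1000 summed counts. Ratios of replicate 2 to replicate 1 used expected counts with TMM scaling and a prior count of 0.5, for genes with a mean TPM of at least 1 and at least 50 summed counts. Exact binomial intervals for these ratios came from the counts. With 1 library on each side there is no replicate check and no p-value across genes. The smallest exact two-sided p that 2 libraries allow in a sign test is 0.5, so no p-value is given.

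A list with at least 5 members at that level was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The percentile describes these libraries only, and members of a cell type list vary together, so independent random genes understate the spread. Correlations between libraries or quantifications are across genes, which are not independent replicates. The X to autosome ratio has a percentile interval from 10000 bootstrap draws of genes. Quantifications were compared on log2(TPM + 0.1), and a gene differed where the estimates were over 2-fold apart the same way in both libraries. Sequence sharing was computed from the annotated transcripts as the percent of a gene's 31-base words found in another gene; the threshold of 50% and the length limit of 350 bases were chosen after seeing the data. Other software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

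Named genes followed a rule fixed beforehand: the 10 nuclear protein-coding genes and 5 lncRNA genes with the highest mean TPM; in each list the 3 members with the highest mean TPM and the lowest member; the fixed ratios and isoform genes; the 12 genes with the largest and the 12 with the smallest ratio between the libraries; and the 5 protein-coding genes with the largest disagreement each way between the quantifications. Some genes that meet this rule are not reported here. Genes outside it are said to be chosen after their values were seen. The 42 lists comprised 24 of cell types or regions and 18 of gene groups; 3 genes (Grik4, Meg3 and Rian) stood in a pair of lists each.

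Alternatives were RLE size factors from DESeq2 1.42.0, ERCC totals, deposited TPM with pseudocounts of 0.1 and 1, other floors and filters, FPKM, TPM rescaled over nuclear protein-coding genes, the second quantification, and each replicate left out. The procedures were tested on simulated data. A coefficient of variation of 0.1 was recovered as 0.0999, and as 0.145 (robust estimate 0.101) with 200 genes changed 4-fold. Of 200 genes changed 2-fold between simulated libraries, 50.5% met the 2-fold rule, against 98.5% at 3-fold and 100% at 4-fold, with 10, 6 and 6 of the unchanged genes also called. The simulated libraries for this rule and for the lists used the robust coefficient of variation, 0.0618, for every gene. The common estimate was higher, at 0.104, so these rates may be too favourable, above all for genes with few counts. Of 100 random lists with no shift, 7 lay outside the central 95%, and a shift of -0.30 was recovered as -0.35.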

Results

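Hippocampal RNA from 14-day-old female B6CASTF1/J mice, the hybrid offspring of C57BL/6J and CAST/EiJ parents, was measured by total RNA sequencing. The hippocampus is the cortical structure of spatial and episodic memory, and at this age its synapses and myelin are still being formed. The data comprised 1 group of 2 biological replicates, with 33465393 and 32879872 expected counts. The labels call the source a hippocampal layer without saying which, so which fields each library held is not known. No second condition was analysed, so the design allows a description of the tissue and of how far its replicates lay apart. Levels are given in TPM as mean ± SD (n = 2) unless a replicate is named, and positions are on mm10.

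The most abundant nuclear protein-coding messages were those of the cytoskeleton, translation, synaptic signalling and astrocytes. Cytoplasmic actin (Actb, 1733 ± 0.502) and elongation factor Eef1a1 (1638 ± 12.0) led, followed by Camk2a (1452 ± 153), the calcium-dependent kinase of excitatory synapses on chromosome 18 (60925618 to 60988152). Next came the prohormone-processing enzyme Cpe (1384 ± 24.99), the lipid carrier Apoe (1231 ± 84.5) and the protease inhibitor Cst3 (1222 ± 97.8). The astrocyte glutamate transporter Slc1a2 (1079 ± 143), ferritin heavy chain Fth1 (1075 ± 65.2) and calmodulin 3 (Calm3, 1040.5 ± 11.6) were also among the first 10. Protein-coding genes took 78.8% ± 1.21 of counts but 44.3% ± 1.48 of TPM, since short noncoding RNAs carry much TPM per count; in the second quantification they took 73.2% of TPM.

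In TPM of the first quantification, noncoding RNA was led by the signal recognition particle genes Rn7s1 and Rn7s2, at 27.8% ± 0.192. By counts they took 3.83% ± 0.00571, below the 7.55% ± 0.936 of the mitochondrial ribosomal RNAs. The sequences of Rn7s1 and Rn7s2 are shared in full, so reads cannot be assigned to either. In the second quantification they took 0.000259% of TPM, and small noncoding RNA genes together 0.0649% against 36.7% in the first. The transcription regulator Rn7sk took 0.811% ± 0.00876 of counts. Mitochondrial genes held 9.38% ± 1.2004 of counts, 8.53% in replicate 1 and 10.2% in replicate 2, mostly as mt-Rnr2 (52080 ± 6010 TPM) and mt-Rnr1 (37537 ± 4373 TPM), the ribosomal RNAs of the organelle. Small noncoding RNA genes took 4.96% ± 0.0258 of counts, lncRNA genes 5.22% ± 0.0106 and pseudogenes 1.34% ± 0.00436. The chromosome 1 pseudogenes Gm28661, Gm10925 and Gm28437 had 94829, 81578 and 64998 counts in replicate 1. Each shares 100% of its words with other genes, and the mitochondrial mt-Co1 shares 63.9%. The pseudogene share and the mRNA part of the mitochondrial share are therefore uncertain. Among lncRNAs, Gm26917 (14508 ± 736), the nuclear speckle RNA Malat1 (4007 ± 476), the mitochondrial RNA-processing RNA Rmrp (3765 ± 97.3), Gm42418 (2693 ± 52.1) and the imprinted Meg3 (1161 ± 127) stood highest. Another Rmrp entry at the same locus, classed as a ribozyme, had 2705 ± 2.16. The lncRNA and ribozyme entries share 96.0% and 100% of their words with other genes, so the level and rank of Rmrp are uncertain. Gm26917 and Gm42418 together took 3.00% ± 0.170 of counts. Gm26917 lies on chromosome 17 at 39843013 to 39846341, and Gm42418, at 39846958 to 39848788, lies entirely within an annotated ribosomal RNA gene on the other strand (39846353 to 39848827). In the RefSeq annotation, the ribosomal RNA gene Rn18s-rs5 also covers 68.0% of Gm42418. Counts of Gm42418 are therefore uncertain, and strand use in counting is not given in the sources used here. Whether reads of Gm42418, or of the adjacent Gm26917, come from ribosomal RNA was not tested. Both levels, and the lncRNA share that includes them, are uncertain as lncRNA expression. ERCC spike-ins held 0.426% ± 0.00488 of counts.

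In all, 14792 of 55536 annotated genes were detected. These comprised 12892 of 22015 protein-coding genes, 669 of 10155 lncRNA genes, 615 of 13525 pseudogenes, 183 of 5737 small noncoding RNA genes and 15 of 37 mitochondrial genes.

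Most markers of hippocampal neurons were detected: 7 of 7 for CA1, 6 of 7 for CA2, 6 of 6 for CA3 and 6 of 7 for dentate granule cells. Markers of CA3 pyramidal cells had a median of 30.985 ± 5.17, with the calcium-binding Cpne4 at 57.1 ± 6.07, the apoptosis regulator Bok at 39.4 ± 2.96 and the adhesion molecule Nectin3 at 33.9 ± 6.24. CA1 markers had a median of 21.9 ± 1.14 and were led by Wfs1 (59.8 ± 13.9), Mpped1 (58.6 ± 4.84) and Fibcd1 (46.3 ± 6.34). CA2 markers had a median of 10.2 (11.4 and 11.3 in the libraries taken singly), led by the calmodulin-binding Pcp4 (143 ± 6.15), Necab2 (50.005 ± 8.25) and the signalling regulator Rgs14 (30.3 ± 3.97); Map3k15 was lowest at 0.570 ± 0.0424. Dentate granule cell markers stood at 7.76 ± 0.177, with the fate-determining Prox1 at 50.4 ± 7.37 and the synapse organizer C1ql2 at 21.1 ± 5.02. Mossy cell markers had a median of 5.08 ± 1.41, with Ociad2 (44.6 ± 3.39) and calretinin (Calb2, 38.5 ± 4.03) highest and Csf2rb2 (1.00 ± 0.0212) lowest. GABAergic interneuron markers had a median of 30.5 ± 4.16, and the neuropeptides Cck (236 ± 10.9) and Sst (149 ± 31.3) exceeded Vip (5.03 ± 0.0354).

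Markers of immature neurons and neural progenitors were detected, but levels in bulk tissue do not show which cells express them. Immature neuron markers had a median of 20.7 ± 2.45, with Dpysl3 at 113 ± 9.67, the microtubule-binding Dcx at 33.2 ± 1.86 and the intermediate progenitor factor Eomes lowest at 2.12 ± 1.08. Neural progenitor markers stood at 16.9 ± 1.63, led by the fatty acid carrier Fabp7 (81.0 ± 11.5) and Hopx (37.8 ± 3.55). Proliferation markers were low, with a median of 1.75 ± 0.0813; Pcna (21.1 ± 1.80), which also serves DNA repair, was well above Top2a (3.54 ± 1.00) and Birc5 (1.07 ± 0.559). Cajal-Retzius markers had a median of 1.41 ± 0.202, although Reln, which interneurons also express, reached 35.8 ± 3.00.

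Among glia, astrocyte markers had the highest median, 72.6 ± 4.29, at a percentile of 90.2 among expressed protein-coding genes; behind Slc1a2 stood aldolase C (Aldoc, 323 ± 49.1) and the glutamate transporter Slc1a3 (215 ± 33.6). Myelinating oligodendrocyte markers had a median of 56.7 ± 0.223, with myelin basic protein (Mbp) at 897 ± 6.05, Mobp at 163 ± 2.81 and the acetylaspartate-cleaving enzyme Aspa at 1.93 ± 0.389. Oligodendrocyte precursors stood at 16.5 ± 0.0919, led by the lineage factor Olig1 (84.9 ± 2.69) and the growth factor receptor Pdgfra (38.2 ± 5.33). Differentiating oligodendrocytes stood at 13.0 ± 0.385, led by Bcas1 (53.8 ± 1.68) and the receptor Gpr17 (48.5 ± 12.7). Microglial markers had a median of 17.5 ± 1.36, with the receptor Csf1r at 35.3 ± 2.47 and P2ry12 at 33.4 ± 5.15. Endothelial markers stood at 15.0 ± 0.120, led by the tight junction protein Cldn5 (32.4 ± 0.771), and markers of pericytes and smooth muscle at 7.98 ± 1.31, led by Rgs5 (45.8 ± 2.20). Globin and other blood transcripts had a median of 175 ± 4.14, with Hbb-bs at 245 ± 0.205; Hba-a1 (217 ± 16.5) and Hba-a2 (175 ± 4.14) are near-identical, so their division is uncertain.

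Thalamus and striatum markers were lower than those of CA1 and CA3 neurons. The thalamus list had a median of 4.07 ± 0.912, with Prkcd at 20.3 ± 2.61 and Gbx2 at 0.0400 ± 0.0283, and the striatum list 3.18 ± 0.598, with Ppp1r1b at 18.5 ± 2.52 and the dopamine receptor Drd1 at 1.26 ± 0.0141. The neocortex list stood at 13.6 ± 1.05, led by Lhx2 (43.2 ± 0.573), which hippocampal cells also express. Fibroblast and meningeal markers had a median of 16.4 ± 4.71, led by Igf2 (79.3 ± 27.4; 61.9% of its sequence words are shared with another gene) and collagen genes Col1a1 (21.2 ± 6.55) and Col1a2 (18.8 ± 4.80). Choroid plexus and ependymal markers differed most between the libraries: their medians were 7.13 and 3.17 in replicate 1 against 0.255 and 0.865 in replicate 2.

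**Figure D1:**
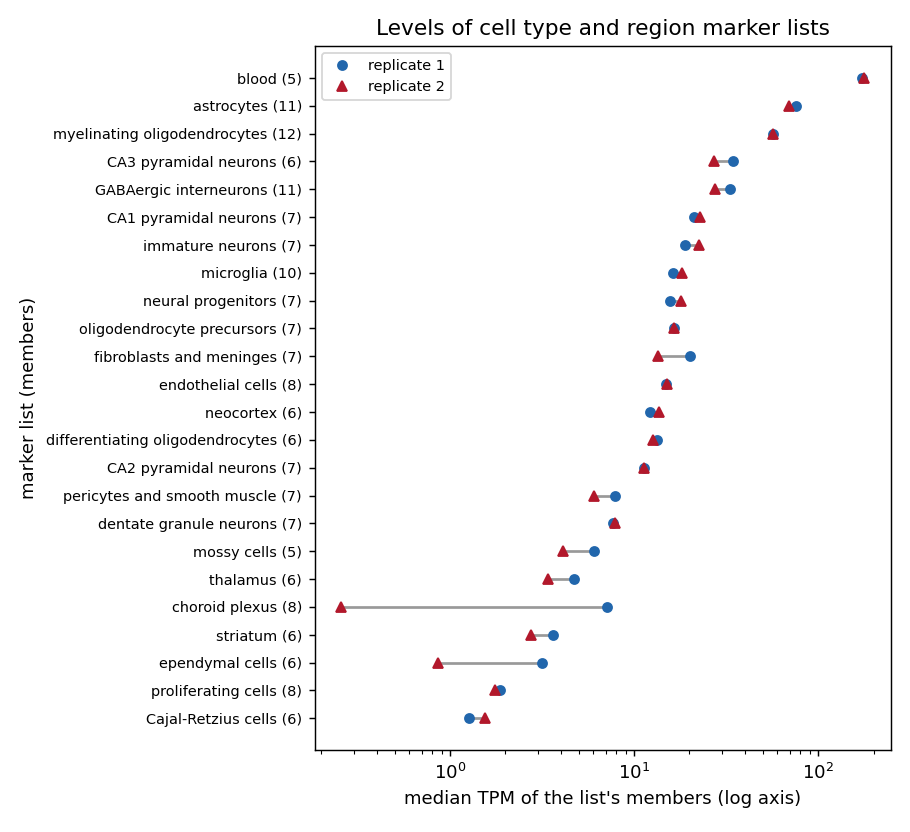
Median TPM (log axis) of the members of each of 24 cell type or region lists in replicate 1 (circles) and replicate 2 (triangles), with the number of members in brackets and a line joining the libraries. Choroid plexus (7.13 against 0.255) and ependymal (3.17 against 0.865) lists have the widest gaps.

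Synaptic vesicle and postsynaptic density genes were abundant, and receptor and channel genes less so. Synaptic vesicle genes had a median of 319 ± 19.1, with Syp at 791 ± 48.4, the vesicular glutamate transporter Slc17a7 at 691 ± 27.3 and the fusion protein Snap25 at 627 ± 44.5, and postsynaptic density genes 245 ± 15.4, with Nrgn at 734 ± 33.9 and Camk2b at 449.6 ± 24.1 behind Camk2a. GABA-A receptor subunits stood at 48.1 ± 3.16, with the extrasynaptic subunit Gabrd lowest at 5.62 ± 1.54. Ionotropic glutamate receptors stood at 40.0 ± 1.26, from Gria1 (252 ± 0.396), Gria2 (231 ± 8.89) and Grin1 (182 ± 0.537) down to Grik1 (6.92 ± 0.841). Voltage-gated potassium channels had a median of 33.025 ± 0.293, with Kcnq3, a subunit of the M current channel, at 56.2 ± 5.15.

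Metabolic and general groups spanned a wide range. Mitochondrial mRNAs had a median of 2415 ± 328, led by mt-Co1 (5910 ± 579) and mt-Cytb (3673 ± 378); nuclear genes of oxidative phosphorylation 297 ± 11.5, led by Atp5b (784 ± 66.9); housekeeping genes 587 ± 8.91, with Gapdh at 900.3 ± 62.6; and ribosomal protein genes 181 ± 1.10, led by Rpl41 (884 ± 21.6). The level of mt-Co1 is uncertain, since 63.9% of its words are shared with other genes. Cholesterol synthesis genes stood at 35.8 ± 1.61, with the synthase Hmgcs1 at 203 ± 22.0. Histone genes, whose main messages lack poly(A) tails and so are kept in total RNA, had a median of 12.4 ± 1.65, with Hist1h4h at 119 ± 24.6; many copies share sequence and are uncertain. Non-polyadenylated RNAs had a median of 29718 ± 193, with the telomerase RNA Terc lowest at 4.41 ± 1.65. Nuclear lncRNAs stood at 362 ± 39.4, with Neat1, the paraspeckle RNA, at 11.2 ± 3.30. Imprinted genes had a median of 41.6 ± 4.13, led by Meg3, Rian (554 ± 58.1) and Nnat (478 ± 97.7), with Dlk1 at 0.625 ± 0.290. Circadian clock genes stood at 19.6 ± 1.63, led by Tef (81.4 ± 1.94), Cry2 (41.5 ± 4.04) and Per1 (36.0 ± 0.863). Immediate early genes of neuronal activity had a median of 7.64 ± 0.251, with Arc at 29.1 ± 3.40, Egr1 at 28.8 ± 0.0141 and Fosb at 2.12 ± 0.764. Heat shock and stress genes stood at 11.3 ± 0.880, from Hspa8 (891 ± 186) to Atf3 (0.310 ± 0.113). TPM rescaled over nuclear protein-coding genes raised list medians, that of astrocytes to 165, and the median of non-polyadenylated RNAs was 1.23 in the second quantification.

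Pairs of genes whose balance is known to shift with postnatal age or cell type were compared within each library. The mature chloride exporter Slc12a5 exceeded the importer Slc12a2 by 7.07 ± 0.738 times, or 4.71 times in expected counts. NMDA receptor subunit messages were close: Grin2b over Grin2a was 1.23 ± 0.0630 in TPM, 1.92 in expected counts and 0.988 in the second quantification, so the order depended on the quantification. Gria2 over Gria1 was 0.918 ± 0.0367. Slc17a7 stood 67.2 ± 13.6 times above Slc17a6, the transporter of thalamic and other subcortical neurons. Among GABA-synthesizing enzymes, Gad1 over Gad2 was 3.09 ± 0.280 (1.30 in expected counts). Slc1a2 over Slc1a3 was 5.04 ± 0.121 (12.1 in expected counts) and Snap25 over Gapdh 0.697 ± 0.000934, against 0.321 in the second quantification and 1.97 in expected counts.

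Xist was abundant, and Y-linked genes were at or near 0 in the first quantification but not all in the second. The X inactivation RNA Xist, on chromosome X at 103460366 to 103483254, had 83.8 ± 6.60 TPM; its antisense partner Tsix had 0.555 ± 0.0495, a ratio of 152 ± 25.5 (577 in expected counts) that is uncertain without known strand use. Of the Y-linked genes in the first quantification, Ddx3y, Uty, Eif2s3y and Usp9y were at 0 and Kdm5d at 0.02 ± 0.0141, below the floor of 3 counts per kb; the median of the list of Xist, Tsix and Y-linked genes was 0 in both libraries. In the second quantification the median of this list was 0.941, with Uty at 3.30 and 3.22 TPM and Kdm5d at 0.991 and 0.891. Outside the list, Gm47283, annotated on chromosome Y, was at 0 in the first quantification and at 346 and 214 TPM in the second. It shares 46.8% of its words with other genes, so its level is uncertain. The median of 432 X-linked protein-coding genes was 0.912 times that of 12453 autosomal genes (interval over genes 0.806 to 1.03), with 0.930 in replicate 1 and 0.899 in replicate 2. With no expression floor the ratio was 0.145.

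Most genes had nearly the same level in both libraries. Across 14715 genes, 78.9% lay within 1.2-fold, and the central 95% of log2 ratios ran from -0.61 to 0.49. The common coefficient of biological variation was 0.104 over 17910 genes, and its robust estimate over 8235 well-counted genes was 0.0618. Log2 levels had a Pearson correlation of 0.981 and a Spearman correlation of 0.988 across genes, which are not independent replicates. For 35 spike-ins with at least 50 counts the SD of the log2 ratio was 0.23.

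The clearest gap between the pools was in choroid plexus, the epithelium that secretes cerebrospinal fluid: every one of its 8 listed genes was lower in replicate 2, with a median log2 ratio of -4.88. Ttr, the thyroid hormone carrier made in bulk by this epithelium (chromosome 18, 20665280 to 20674321), had 1375 TPM in replicate 1 and 5.62 in replicate 2, from 34185 and 139 counts, a 227-fold ratio (counting interval 193 to 271). The folate receptor Folr1 was 39.7-fold (18.4 to 135) and the water channel Aqp1 35.9-fold (20.3 to 79.2) lower in replicate 2. The potassium channel Kcnj13 was 44.9-fold lower (17.6 to 255.5, from 3 counts). Sostdc1, the most abundant listed member after Ttr, had 14.7 and 1.99 TPM, and Otx2, the choroid plexus transcription factor, 4.44 and 0.130. The summed TPM of the list was 1437 and 9.86. Deposited TPM with a pseudocount of 1 put the list at -2.67.

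Further genes with ratios among the 12 smallest, named for that rank, included epithelial transporters. The bicarbonate cotransporter Slc4a5 was 84.8-fold lower in replicate 2 (33.5 to 482, from 3 counts), the potassium channel subunit Kcne2 74.4-fold (19.6 to 4426, from 1 count) and the secreted peptide gene 1500015O10Rik 29.1-fold (17.1 to 59.1). Mfrp (log2 ratio -5.79) was also lower in the second quantification (-3.56), while Tmem72 was at -5.14 in the first and -0.35 in the second, so its difference is uncertain. Ependymal genes, which serve the motile cilia of the ventricle lining, had too few members at the level required for a test of the list; Foxj1, the master regulator of these cilia, had 5.80 TPM in replicate 1 and 2.75 in replicate 2, and Rsph1 9.02 and 5.19. Fibroblast and meningeal genes were lower in replicate 2 by a median log2 ratio of -0.52, 6 of 7 members in that direction, with Igf2 at -0.61 and Lum at -0.91.

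Among genes at least 2-fold apart, those higher in replicate 2 were fewer than those lower in it. The tetraspanin Tspan10, on chromosome 11 at 120442644 to 120446950, had 1 count in replicate 1 and 114 in replicate 2, a ratio of replicate 1 to replicate 2 of 0.0121 (0.000204 to 0.0462), and its log2 ratio was 6.36 in the first quantification and 6.24 in the second. The neurexin ligand Nxph3 stood at 1.46 and 3.87 TPM (2.82-fold higher), the transcription factor Tshz2 at 3.74 and 9.37 (log2 ratio 1.47), the invariant chain Cd74 at 0.660 and 1.48 (1.39) and the cell cycle inhibitor Cdkn2b at 0.910 and 2.04 (1.25). In all, 150 genes differed at least 2-fold, 38 higher and 112 lower in replicate 2. The count was 78 (15 and 63) where both quantifications had to meet the rule and 95 without genes that share at least 50% of their sequence words, both chosen after seeing the data. It was 244 with no TPM filter, 44 at a mean TPM of at least 5 and 88 on deposited TPM with a pseudocount of 1.

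Several of the widest ratios belonged to genes whose reads are shared with copies or overlapping genes and are uncertain. Gm14288 (4.67 and 0 TPM), 1700047I17Rik2 (4.02 and 0) and Pagr1a (11.9 and 0.260), all lower in replicate 2, share 100%, 100% and 93.2% of their words with other genes. The second quantification gave Pagr1a a similar log2 ratio (-6.20 against -6.35), but -0.46 for Gm14288 and almost no TPM for 1700047I17Rik2 in either library. Gm20388, a readthrough model with 0.02 and 395 counts, shares 99.3%, and Gm20521, the Myl12b model on chromosome 17 at 70974119, Gm10273, Gm3435 and Gm20517 share 97.7%, 97.2%, 96.7%, 94.6% and 74.0%. In the second quantification the log2 ratios of Gm20388, Gm3435, Gm20517 and mt-Co2 were 1.06, 1.19, 0.99 and 1.11. The mitochondrial gene mt-Co2 (37.4 and 145 TPM) shares 100% of its words with another gene; the unshared mt-Nd1 stood at 2862 and 3452 TPM.

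**Figure D2:**
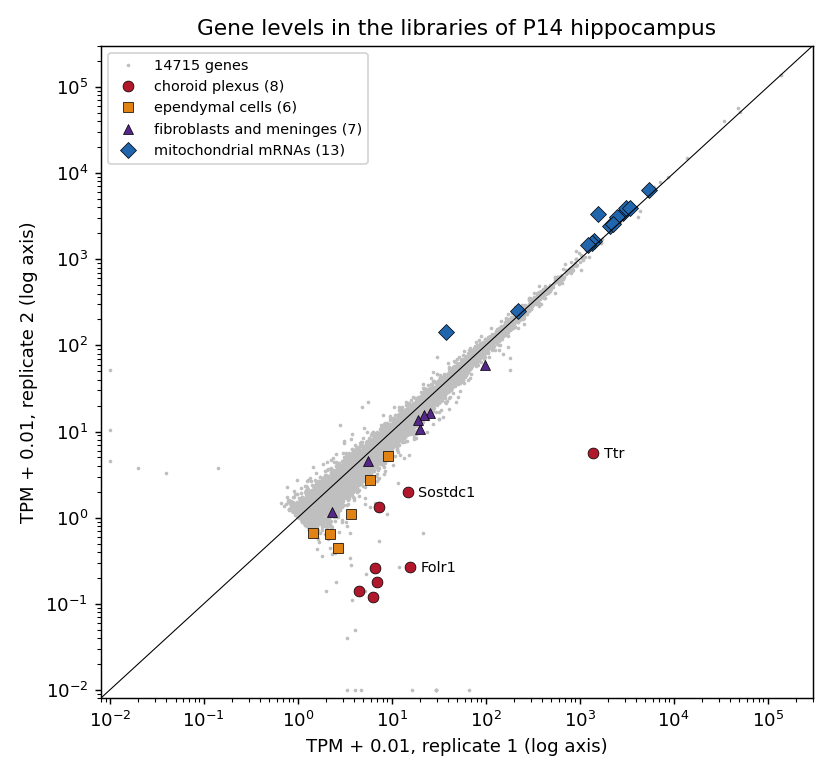
TPM + 0.01 of 14715 genes in replicate 1 (x) and replicate 2 (y), both log axes, with choroid plexus (8), ependymal (6), fibroblast and meningeal (7) and mitochondrial mRNA (13) genes marked and the line of equal level drawn. Ttr lies farthest below the line among the marked genes, at 1375 and 5.62 TPM.

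Smaller shifts ran through neuronal and glial lists. Dentate granule markers were higher in replicate 2 by a median log2 ratio of 0.37 (6 of 7 members), with C1ql2 at 0.59 and Prox1 at 0.37. Microglial (0.28, 8 of 10), immature neuron (0.27, 6 of 7), astrocyte (0.24, 10 of 11), CA1 (0.22, 6 of 7), neocortex (0.16) and endothelial (0.15) markers were also higher, and CA3 (-0.14, 5 of 6 lower), GABAergic (-0.13, 8 of 11 lower) and differentiating oligodendrocyte (-0.19, 3 of 6 lower) markers lower. All 13 mitochondrial mRNAs were higher in replicate 2, with a median of 0.31. Among gene groups, postsynaptic density (0.21), circadian clock (0.21), immediate early (0.15), GABA-A receptor (0.15), potassium channel (0.14) and ribosomal protein (0.10) genes were higher, and nuclear lncRNAs (-0.09), imprinted (-0.17) and histone (-0.20) genes lower. These lists, with choroid plexus and meninges, make 22 of 38 outside the central 95% of matched random lists, against 1.9 by chance for independent genes; members vary together, so the chance number is too low. The remaining lists lay inside: ionotropic glutamate receptors and myelinating oligodendrocytes at 0.11 each, oligodendrocyte precursors 0.11, blood 0.15, non-polyadenylated RNAs 0.13, housekeeping 0.06, CA2 0.04, oxidative phosphorylation 0.02, synaptic vesicle 0.01, pericytes -0.02, cholesterol synthesis -0.03, striatum -0.08, neural progenitors -0.10, heat shock -0.10, mossy cells -0.11 and proliferating cells -0.19. Signs for CA2, oligodendrocyte precursor, blood, synaptic vesicle, oxidative phosphorylation and housekeeping lists flipped under at least 1 other scaling. The median of all genes was 0.01 under TMM scaling and -0.09 in deposited TPM. On deposited TPM with a pseudocount of 0.1 the shifts of most lists moved in the same direction as that median. Potassium channel and ribosomal protein genes were at 0.00 each, GABA-A receptors 0.03, neocortex 0.04, immediate early genes and endothelial cells 0.05 each, astrocytes and the postsynaptic density 0.10 each, immature neurons 0.11, CA1 0.12 and microglia 0.17. Nuclear lncRNAs were at -0.22, GABAergic neurons at -0.20 and CA3 at -0.26. Without the most shifted member of each list, CA3 was at -0.09, potassium channels at 0.09 and differentiating oligodendrocytes at 0.00. Of 8 other settings, neocortex, potassium channel and differentiating oligodendrocyte lists lay outside the matched range in 5, CA3 and immediate early lists in 6, and endothelial and ribosomal protein lists in 7. Without genes that share sequence, an alternative chosen after seeing the data, the histone shift was -0.10.

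**Figure D3:**
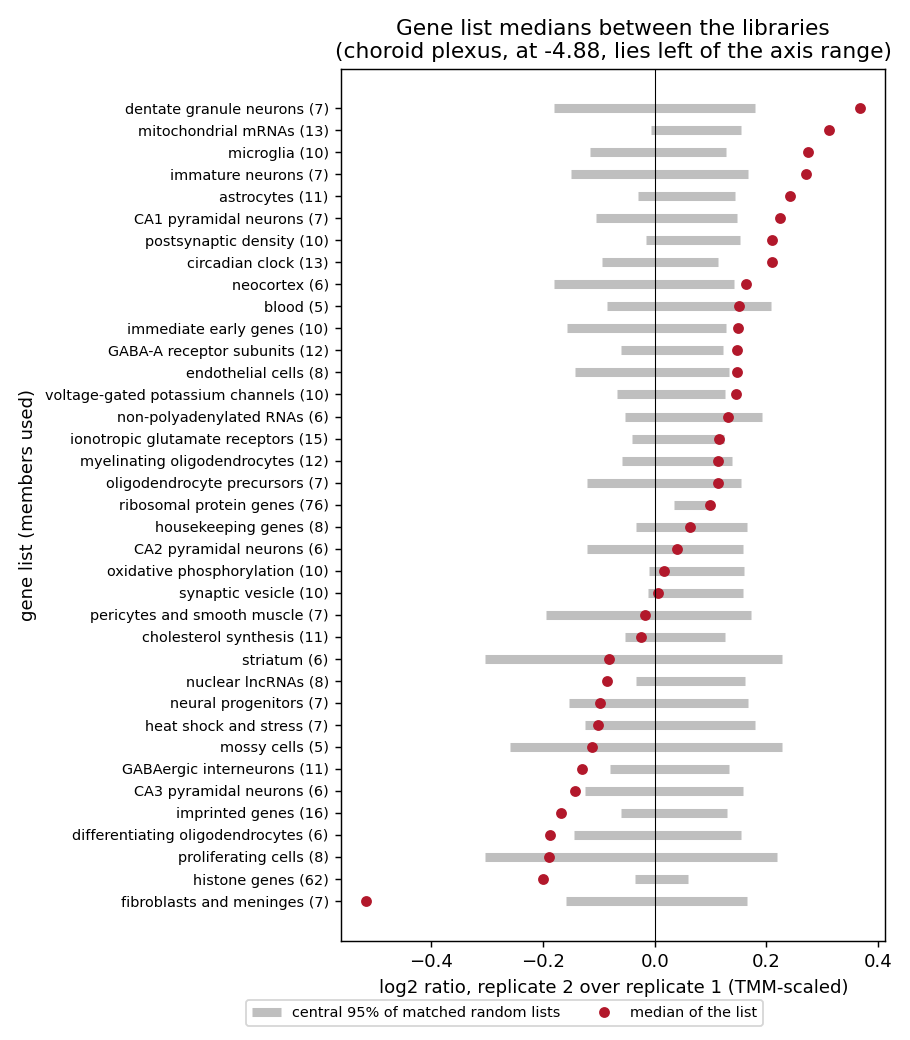
Median log2 ratio of replicate 2 over replicate 1 (TMM-scaled) for each gene list (points; members used in brackets) with the central 95% of 10000 matched random lists (grey bars). Dentate granule neurons lie highest at 0.37 and fibroblasts and meninges lowest among those drawn at -0.52, while choroid plexus, at -4.88, is left of the axis range.

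The same libraries had been quantified in 2 ways, and the estimates differed most for short and duplicated transcripts. Rn7sk, Rmrp and mt-Atp8, abundant in the first quantification, were at 0 in the second. Among protein-coding genes, Snurf (1031 ± 74.8 TPM in the first), Rps12-ps3 (159 ± 10.03), Rpl10-ps3 (135 ± 21.02), Hist2h2aa2 (115 ± 0.948) and Gm11273 (29.2 ± 1.58) were at 0 in the second. Conversely Gm47283, Gm21897, Gm45837 and Gm27027 were at 0 in the first and had 346 and 214, 45.7 and 39.5, 14.6 and 21.6, and 17.4 and 17.4 TPM in the second. Hist2h2aa1, a neighbour of Hist2h2aa2 on chromosome 3, had 3.47 and 0 TPM in the first against 230.07 and 221 in the second. Each of these 10 protein-coding genes shares at least 46.8% of its words with another gene, so its level is uncertain.

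Ranks of genes had a Spearman correlation of 0.891 between quantifications in each library, and of 0.919 for genes with a mean TPM of at least 1; across 141767 transcripts it was 0.741 and 0.738. The second quantification gave a median 1.57 times the TPM of the first. Of 16880 genes, 2736 differed over 2-fold the same way in both libraries, 2275 higher and 461 lower in the second. After rescaling to nuclear protein-coding genes the count was 1411 (883 and 528), and at a TPM floor of 5 it was 1468.

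For 15 of 20 neuronal and myelin genes both quantifications named the same leading transcript. Snap25-201 took 83.6% ± 1.52 of Snap25, Gria1-201 75.8% ± 1.09 of the AMPA receptor gene Gria1, Mapt-204 72.1% ± 1.47 of the tau gene Mapt, Clta-205 69.7% ± 0.569 of the clathrin light chain gene Clta and Gria3-201 68.9% ± 2.67 of Gria3. Camk2a-203 took 64.2% ± 0.754 of Camk2a, Dlg4-203 61.0% ± 1.11 (29.9% ± 1.80 in the second quantification) and Gria2-202 57.2% ± 0.615. Leading shares were lower for Bdnf (44.6% ± 5.55), Map2 (41.9% ± 0.147), Grin1 (33.5% ± 0.583) and Ank3 (20.8% ± 0.752). Shares of expected counts gave 32.8% for Ank3.

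The quantifications named different leading transcripts for 5 genes. For Mbp it was Mbp-211 (60.9% ± 0.583) in the first and Mbp-201 (27.7% ± 1.47) in the second, where Mbp-211 took 17.9% ± 2.70. For Dnm1, the synaptic dynamin, it was Dnm1-201 (35.6% ± 0.991) and Dnm1-205 (35.3% ± 2.00). Homer1-203 (30.9% ± 1.06) and Homer1-207 (25.8% ± 1.08), and Gria4-203 (37.1% ± 0.686) and Gria4-201 (35.6% ± 5.49), were further pairs. Over the 20 genes the median SD between libraries was 1.02 points and the median difference between quantifications 4.26 points.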

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

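The requirement that both quantifications meet the 2-fold rule and the removal of genes sharing sequence were chosen only after the result was seen; the other alternatives were chosen before. Among results that answer a comparison, Grin2b over Grin2a crossed 1 in the second quantification and no other direction turned. Of 66 values of these results under alternatives, 43 stayed within the limit set for each. The limit was the spread between replicates for levels and ratios and 1.5 times for a count. For the choroid plexus shift it came from the width of the matched random range. Any change of the coefficient of variation counted as moved. Leaving out a replicate could not move the protein-coding share or a gene ratio beyond the SD, so those values say nothing about stability.

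The protein-coding share was 44.3% of TPM, which weights short RNAs more. The coefficient of biological variation of 0.104 was 0.104 with RLE factors, 0.109 with ERCC totals, 0.115 with no count filter, 0.0899 at 100 counts or more, 0.101 for nuclear protein-coding genes and 0.101 in the second quantification. Genes 2-fold apart numbered 88 on deposited TPM with a pseudocount of 1, 244 with no TPM filter, 44 at a TPM of at least 5, 78 under both quantifications and 95 without genes sharing sequence. RLE factors kept 148 of the 150 genes and ERCC totals 146, and 79 of the 171 genes of the second quantification were among them, of which Gm14308 differed the other way (log2 ratio -1.29 in the first, 1.22 in the second) and leaves 78. ERCC totals gave 163 genes, 129 of them lower in replicate 2, and deposited TPM with a pseudocount of 0.1 gave 192 with 160 lower. The choroid plexus shift was -4.51 and -2.67 on deposited TPM with pseudocounts of 0.1 and 1, which pull low values together, and -4.59 without its most shifted member, Ttr. Grin2b over Grin2a was 1.92 in expected counts and 0.988 in the second quantification, and Slc12a5 over Slc12a2 4.71 and 6.26. The X to autosome ratio was 0.878 at a floor of 5 and 0.145 with no floor, where silent genes enter. Genes differing between quantifications numbered 1468 at a floor of 5 and 1411 after rescaling. The causes of the other differences were not tested.

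Of the 22 lists outside the matched range, 15 stayed outside in all 8 other settings and 21 kept their sign; differentiating oligodendrocytes did not. Among values of single lists, genes or ratios, 399 stayed within the limit set for each and 222 moved beyond it. For levels, shares and ratios within a library the limit was the replicate spread. For list shifts it came from the width of the matched random range, so their values do not measure replicate spread. Those that moved were mostly list levels and isoform shares under another unit or quantification. With either replicate left out, all 20 isoform shares, 9 gene ratios and 3 shares of gene classes stayed within the replicate spread. Leaving out a replicate could not move these beyond the SD, so that part of the 399 says nothing about stability. Of list levels, 36 and 35 stayed and 6 and 7 moved, with little more room to move. Leaving out a replicate is not possible for ratios between the libraries, and the choroid plexus list had too few members at a TPM of at least 5. No paired analysis was possible because the data hold 1 group. Depth limits genes with few counts: ratios resting on 1 to 3 counts have intervals spanning over an order of magnitude.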

Other observations

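The tests of scaling, of another brain region, of transcript length and of sequence shared in part, for transcripts at 0 and for genes 2-fold apart, were chosen only after the result was seen. Genes named in this section outside the fixed lists were chosen after their values were seen. Members of the second choroid plexus list differed widely in how far they were lower in replicate 2. The lipid-producing enzyme Enpp2, which oligodendrocytes also make, had 183 TPM in replicate 1 and 51.3 in replicate 2, a 3.36-fold ratio (3.23 to 3.51). The prolactin receptor Prlr was 3.54-fold lower (2.86 to 4.43), the collagen gene Col8a1 9.78-fold (7.09 to 14.2), the sulfatase Sulf1 7.85-fold (6.38 to 9.84) and the calcium channel Trpv4 5.61-fold (3.75 to 8.99). The carbonic anhydrase Car12 was 1.25-fold lower (1.15 to 1.36), the kinase Stk39 1.17-fold (1.09 to 1.25) and the transporter Slc29a4 1.06-fold (0.992 to 1.14). All 6 genes of the fixed ependymal list had negative log2 ratios, with Tmem212 at -2.46, Ccdc153 and Dynlrb2 at -1.62 each and Tekt4 at -1.17, but too few had the level required and the list was not tested.

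Of the 13 circadian clock genes, 12 were higher in replicate 2, with log2 ratios from 1.02 for Ciart, 0.72 for Dbp and 0.59 for Nr1d1 to 0.03 for Per2, and Clock was at -0.04. Among 16 imprinted genes, 15 were lower in replicate 2, with Airn at -0.65, Peg10 at -0.64, Nnat at -0.32 and Snrpn, the exception, at 0.03. Of 62 histone genes, 48 were lower; their median log2 ratio of -0.20 was -0.10 without genes that share sequence. The chaperone Hspa5 of the endoplasmic reticulum had 152 and 80.5 TPM, a log2 ratio of -0.79. Eomes, a marker of intermediate progenitors in the dentate gyrus, was higher at 1.21, from 99 and 213 counts.

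The choroid plexus gap was weighed first with a second list: 24 genes of this epithelium, fixed before its values were looked at, of which 20 had the level required; all 20 were lower in replicate 2, 12 of them at least 2-fold, with a median log2 ratio of -1.38 against a matched range of -0.13 to 0.10. Scaling moves all genes alike, and under ERCC totals the median was -0.05 for all genes and -4.94 for the first list, which argues against it. The first list stayed at -4.51 or lower under TMM, RLE and ERCC scaling and on deposited TPM with a pseudocount of 0.1. A pseudocount of 1 gave -2.67. Division of reads was argued against by -4.86 in the second quantification. Neocortex or striatum in place of hippocampus was argued against by medians of 0.16 and -0.08 for their lists. The neocortex list nevertheless lay outside its matched range, so small differences in dissection are not addressed. The thalamus list had too few members at the level required and is left out. These values may reflect choroid plexus tissue taken along with the hippocampus of replicate 1. However, 16 of the 20 members, and 3 of the 8 genes of the first list, had a TPM of at least 1 in replicate 2 too. Whether that signal came from other cells or from choroid plexus in replicate 2 was not tested. No biological explanation was tested, since the design gives 1 group; a difference between the mice stays open.

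Transcripts at 0 in the second quantification were weighed next: 563 of 15452 genes with a mean TPM of at least 1 in the first. Of genes whose longest transcript is under 350 bases, 93.1% were at 0, against 0.861% of longer ones, where 120 of the 129 at 0 were under 1000 bases (9.90% of that length), which may reflect an assumed fragment length near 343.1 bases. Exact copies in another gene were held by 6.57% of the genes at 0, which argues against them as the whole cause. Among the longer genes at 0, 94.6% shared at least 50% of their words with another gene, against 5.18% of those not at 0, so shared sequence is a candidate explanation for that part. Among genes under 350 bases, 55.3% of those at 0 shared that much, against 28.1% of those not at 0. Length and shared sequence are therefore not separated for the short genes. No biological explanation was tested, as both estimates come from the same RNA.

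Genes 2-fold apart under the first quantification alone were weighed last. Of these 72 genes, 63.9% shared at least 50% of their words with another gene, against 11.5% of the 78 found under both quantifications and 6.06% of all 14715 genes. Their differences may therefore come from reads shared between copies or overlapping genes and divided differently in each library. The remaining 26 genes have no shared sequence at that threshold, and were not weighed further; no biological explanation was tested.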
